A study of Mus musculus with 6 samples.

How the data were processed

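The series holds 6 RNA sequencing libraries of muscle satellite cells, 2 each of Jmjd3 KO, Utx KO and Tdt control. The submitters' processing notes name cutadapt 2.6, Salmon 1.1.0 and DESeq2 1.28.1, without saying what each was used for, and the builds mm10 and GRCm38. The deposited quantification files give, per the file headers, TPM and estimated counts (estimated reads per transcript) with transcript lengths. The authors' deposited comparison tables give, per the file headers, a mean signal per gene (base mean of normalised counts), log2 fold changes with their standard errors, p-values and adjusted p-values. Those fold changes appear shrunken, by a method that is not stated.

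Estimated reads were summed per gene through GENCODE M21 (GRCm38) and rounded. The annotation release used for the deposited files is not given in the sources used here, and for transcripts shared with M21 the lengths in them equal those of M21. Library totals ran from 53750675 to 77675388 estimated reads. Nothing in the labels says that replicates came from separate animals, so p-values of single genes measure only the spread between these samples. Correlations and list tests at a fixed correlation were taken across genes, which are not independent replicates. The tests and intervals for shares of called genes also counted genes. All 6 libraries entered 1 fit of edgeR 4.0.16 (R 4.3.3) with TMM normalization, its filter for low counts and a term for genotype, and the quasi-likelihood test was used. This left 17084 genes, a common biological coefficient of variation of 0.0844, 3 residual degrees of freedom and 4.61 prior degrees of freedom. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, over all genes tested in a comparison. The comparisons were Jmjd3 KO with Tdt control, Utx KO with Tdt control and Jmjd3 KO with Utx KO. CPM are read counts scaled by the normalised library size, log2 fold changes are given ± SE, and means of CPM ± SD.

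The rule for named genes was set before the data were examined. Kdm6b, Kdm6a and Uty were named in every comparison, and Has2, Pax7, Myf5, Myod1 and Myog in both knockout comparisons with the control. Some genes that this rule names are not reported here. In each comparison the 10 largest log2 fold changes in each direction were named, among called genes with a mean over the 6 libraries of at least 5 CPM and with both libraries of a group on the same side of both libraries of the other. Symbols that are Gm numbers, Rik clones or pseudogenes were left out. In each gene list described, up to 4 members with the smallest p were named. Other genes named were chosen after their values were seen.

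The 30 gene lists, written from general knowledge before the data were examined, held 861 entries, of which 860 matched the annotation (Ezhip did not). They covered quiescence-associated, muscle differentiation, mature fibre, hyaluronan, extracellular matrix, interferon-response, NF-kB, DNA replication (S phase), G2 and mitosis, ribosome biogenesis, respiratory chain, glycolysis, unfolded protein response, p53, immediate early, Notch, TGF-beta and BMP, Hox, histone H3 site regulator and cholesterol synthesis genes. The others were markers of fibro-adipogenic, endothelial, macrophage and monocyte, neutrophil, lymphoid, mural, Schwann, tenocyte and erythroid cells, and sex-linked genes. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a fixed correlation between genes of 0.01, adjusted over the 90 tests. A correlation estimated per list and limma's fry were alternatives. The test with an estimated correlation rests on the 3 residual degrees of freedom, so a list that it does not call is not shown to be unchanged. The unfolded protein response list in Utx KO had an estimated correlation of -0.0025, below 0.01. Its unadjusted camera p was still 0.0185 with that correlation, against 3.41e-05 at the fixed one. Within a list, genes were also adjusted over the list alone.

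The methods were tested on simulated data with 200 changed genes. At folds of 1.5, 2 and 4, edgeR recovered 68.7%, 61.2% and 86.4% of them in Jmjd3 KO against Tdt control, 67.2%, 80.6% and 87.9% in Utx KO against Tdt control, and 40.3%, 65.7% and 90.9% in Jmjd3 KO against Utx KO. False calls were above 5%, at 12.4% (21 of 169), 10.5% (19 of 181) and 9.40% (14 of 149) of the calls. Lists of 40 genes shifted by 0.3 (log2) had camera p of 5.00e-20, 1.47e-19 and 9.89e-16, and unshifted lists 0.579, 0.310 and 0.658. The simulated genes were drawn independently, so this does not test camera on lists whose genes vary together. Estimated correlations of the real lists ran from -0.234 (lymphoid) to 0.775 (G2 and mitosis).

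The alternatives were DESeq2 1.42.0, RLE and upper-quartile normalization, no low-count filter (at least 1 read), a filter of 5 CPM in 2 libraries, transcript length offsets, only the 4 libraries compared, a replicate block, protein-coding genes only, and each library left out in turn. A group left with 1 library was assumed to vary like the other groups. For the shared calls, an adjusted p under 0.1 was also tried. Added after the data were seen were tests without chromosome 11 and without genes of other cell type lists. Pseudogenes were aligned to transcripts with blastn 2.17.0 (identity of at least 80%, coverage of at least 50%). Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. With 2 libraries per group, other splits of the libraries and outlier tests were not run.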

Results

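Total RNA was sequenced from muscle satellite cells, the stem cells that rebuild skeletal muscle, of adult C57BL/6 mice. The tibialis anterior and gastrocnemius had been injured with cardiotoxin, a venom toxin that destroys muscle fibres, and the cells were sorted by fluorescence 30 h later. There were 6 libraries, 2 for each of 3 genotypes. Jmjd3 KO cells lacked JMJD3 (gene Kdm6b) and Utx KO cells lacked UTX (gene Kdm6a), both of them enzymes that remove methyl groups from a repressive site on histone H3, and Tdt control cells were the reference. The libraries held 64928614 and 63607780 estimated reads in Jmjd3 KO, 77675388 and 65893124 in Tdt control, and 53750675 and 59768154 in Utx KO, and 17084 genes were tested. Across genes, which are not independent replicates, log2 CPM (normalised read counts scaled to a common library size) of replicates had Pearson correlations of 0.990 to 0.991, against 0.982 to 0.989 between genotypes. On the first principal component, with 35.1% of the variance, the Tdt control libraries (2.36 and 2.33) lay between Jmjd3 KO (-31.2 and -36.0) and Utx KO (36.7 and 25.8). On the second, with 21.8%, the controls (-25.6 and -30.2) lay apart from Jmjd3 KO (25.6 and 0.635) and Utx KO (17.3 and 12.3).

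The targeted genes set the knockouts apart to different degrees. Kdm6a (ENSMUSG00000037369.17, chromosome X, 18162575 to 18279936 in GRCm38) stood at 7.68 and 7.38 CPM in the Utx KO libraries, 32.8 and 34.0 in Tdt control, and 30.3 and 32.4 in Jmjd3 KO. Its log2 fold change in Utx KO was -2.15 ± 0.06 (SE, 2 libraries per group, adjusted p = 1.02e-05), a level 4.44-fold lower. Kdm6b (ENSMUSG00000018476.7, chromosome 11, 69398508 to 69413675) stood at 15.9 and 16.5 CPM in Jmjd3 KO, 29.9 and 22.7 in Tdt control, and 22.97 and 22.17 in Utx KO. It fell in Jmjd3 KO by 1.62-fold (log2 fold change -0.70 ± 0.12, adjusted p = 0.0243). Kdm6b lost the call without Jmjd3 KO replicate 1 and without Jmjd3 KO replicate 2 (adjusted p from 0.123 to 0.167). Against Utx KO the same libraries gave -0.48 ± 0.12, adjusted p = 0.0501. That comparison called it with RLE size factors (adjusted p = 0.0499), no low-count filter (4.27e-08), protein-coding genes only (0.0394), the 4 libraries alone (0.00821) and DESeq2 (0.00460). It was also called without Tdt control replicate 1 (0.00833) and without Tdt control replicate 2 (0.00763). Each knockout left the other target near the control, with -0.22 ± 0.11, adjusted p = 0.398 for Kdm6b in Utx KO and -0.09 ± 0.06, adjusted p = 0.412 for Kdm6a in Jmjd3 KO, a direction that transcript length offsets turned to 0.11. Uty, the Y-linked relative of Kdm6a, was at 3.67 ± 0.837, 4.62 ± 0.665 and 6.39 ± 0.507 CPM (SD, n = 2) in Jmjd3 KO, Tdt control and Utx KO. Only the direct comparison of the knockouts called it (-0.80 ± 0.18, adjusted p = 0.0350; 0.0513 with a replicate block), apart from Utx KO with no low-count filter (0.47, adjusted p = 0.0165). In that comparison the Y-linked Kdm5d (-0.44, adjusted p = 0.0429) and Ddx3y (-0.40, adjusted p = 0.0490) were lower too. Xist was not called (0.87, adjusted p = 0.107). These 3 genes were added after their values were seen. Kdm5d lost the call without Jmjd3 KO replicate 1 (adjusted p = 0.0765). Uty and Kdm5d were no longer called without Jmjd3 KO replicate 2, without Utx KO replicate 1 and without Utx KO replicate 2 (adjusted p from 0.0816 to 0.231). Ddx3y fell out of the calls without each of the 6 libraries (adjusted p from 0.0613 to 0.287). The files give totals per transcript, so loss of the deleted exons alone could not be read from them. As a check of the libraries, each group held transcripts of both Xist (means of 83.6, 70.5 and 45.9 CPM in Jmjd3 KO, Tdt control and Utx KO) and the Y-linked Ddx3y (20.6, 24.2 and 27.1 CPM).

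**Figure D1:**
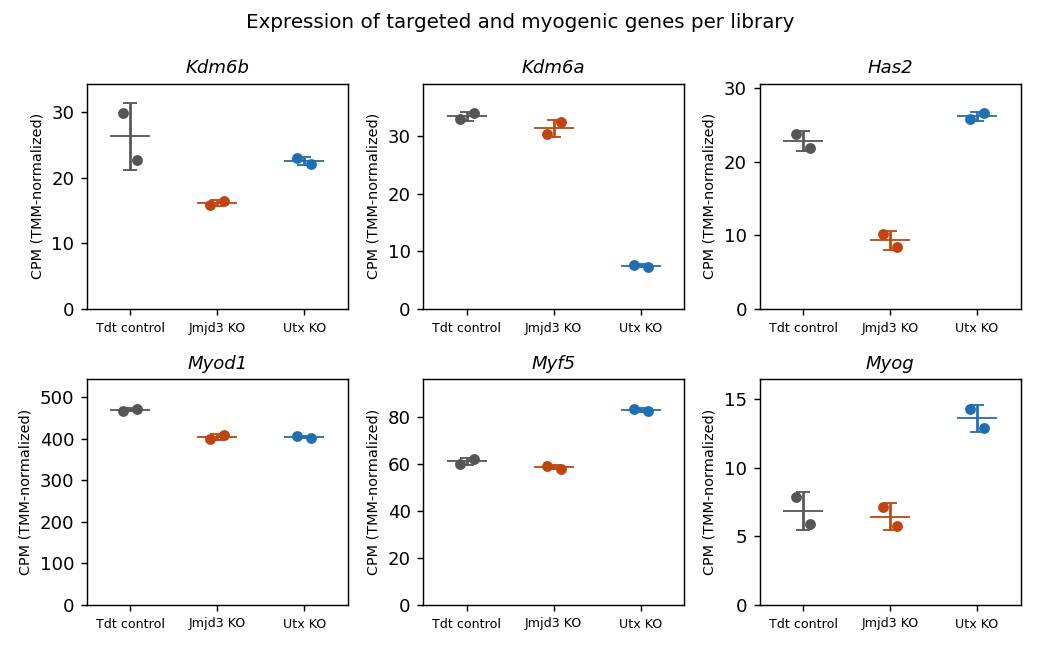
Normalised read counts, CPM (y axes, from 0) of Kdm6b, Kdm6a, Has2, Myod1, Myf5 and Myog in each genotype; points are single libraries, and bars are the mean ± SD of 2 libraries. Kdm6a is lowest in Utx KO (7.68 and 7.38), and Kdm6b and Has2 are lowest in Jmjd3 KO, while Myf5 and Myog are highest in Utx KO.

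Jmjd3 KO was compared with Tdt control to ask which transcripts differ in the sorted cells without JMJD3. Has2, a hyaluronan synthase (ENSMUSG00000022367.7, chromosome 15, 56665627 to 56694539), fell 2.44-fold, from 22.8 ± 1.42 to 9.35 ± 1.27 CPM (mean ± SD, n = 2; log2 fold change -1.29 ± 0.09, adjusted p = 9.16e-04). The chromatin protein gene Hmga2 fell from 99.6 ± 4.79 to 35.7 ± 3.85 CPM, the transcription factor gene Sox11 from 61.9 ± 1.04 to 25.3 ± 0.902, and Tnc, which encodes the matrix glycoprotein tenascin-C, by -0.67 ± 0.04 on the log2 scale (SE). Lpl, which encodes lipoprotein lipase, rose from 59.96 ± 2.89 to 116 ± 10.3 CPM, the kinase gene Cdc42bpa from 50.2 ± 1.44 to 95.6 ± 8.18, and Hdc, which encodes the enzyme that makes histamine, from 13.9 ± 1.54 to 30.2 ± 3.83. The mature fibre, interferon-response, NF-kB and neutrophil lists were higher by camera at its fixed correlation. None was called with an estimated correlation (adjusted p = 0.646, 0.583, 0.483 and 0.646, in that order). Summed over the neutrophil markers, CPM were 367 and 284 in the Jmjd3 KO libraries, against 189 and 205 in Tdt control. Whether other cells in the sort account for the higher neutrophil and mature fibre lists was not tested.

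In all, 513 of 17084 genes changed in Jmjd3 KO (337 higher, 176 lower), 92 of them by at least 2-fold. By the rule for named genes, which 254 higher and 141 lower genes passed, the 10 largest increases were those of AA465934, Borcs8, Il1rn, Acbd4, Hdc, B9d1, Lpl, S100a9, Cdc42bpa and Sgsm2. Their log2 fold changes ran from 3.26 (AA465934, ENSMUSG00000093483.1, chromosome 11, 83291699 to 83294632) down to 0.93, and Il1rn, the interleukin-1 receptor antagonist gene, rose by 1.31 ± 0.15. The 10 largest decreases were those of Vat1l (-1.71 ± 0.10, adjusted p = 3.31e-04), Esm1, Hmga2, Hist4h4, Arl4d, Sox11, Has2, Slfn9, Hebp1 and the imprinted gene Dlk1 (-1.22 ± 0.09, adjusted p = 9.16e-04). Of these 20 genes, AA465934, Acbd4, B9d1, Sgsm2, Arl4d and Slfn9 lie on chromosome 11, on which Kdm6b lies too. The count fell below 513/1.5 without Jmjd3 KO replicate 1 (113), Jmjd3 KO replicate 2 (175), Tdt control replicate 1 (154) and Tdt control replicate 2 (214). It did so too with a replicate block (322) and transcript length offsets (331). DESeq2 (1041) and no low-count filter (1872) raised it. S100a9 and Sgsm2 lost their calls without Jmjd3 KO replicate 1 (adjusted p from 0.0592 to 0.117). S100a9 and Hebp1 were no longer called without Tdt control replicate 1 and without Tdt control replicate 2 (adjusted p from 0.0752 to 0.106). With transcript length offsets Hebp1, Myod1, Myom2, Mef2c, Heatr1, Asns, Herpud1, Gdf15, Tgfb3, Hoxc10, Tyrobp and Pmp22 were not called (adjusted p from 0.0530 to 0.309).

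Of 26 measured genes of mature fibres, 5 rose in Jmjd3 KO (9 adjusted over the list alone), with a median log2 fold change of 0.28 (camera adjusted p = 9.70e-07; adjusted p = 0.646 with an estimated correlation). Among them were the fast myosin gene Myh4 (0.77 ± 0.09, adjusted p = 0.00711), which lies on chromosome 11, the calcium pump gene Atp2a1 (0.27, adjusted p = 0.0141) and the calcium release channel gene Ryr1 (0.58, adjusted p = 0.0158). In the muscle differentiation list, Des, which encodes the filament protein desmin (0.35 ± 0.04, adjusted p = 0.00446), Myom2 (0.40, adjusted p = 0.0370) and Mef2c (0.69, adjusted p = 0.0460) rose among 32 genes (6 higher adjusted over the list alone; median 0.30; camera adjusted p = 4.88e-04, and 0.646 as the adjusted p with an estimated correlation). Of the myogenic regulators, Myod1 (ENSMUSG00000009471.4, chromosome 7, 46376474 to 46379099) fell from 471 ± 2.91 to 405 ± 7.13 CPM (-0.22 ± 0.04, adjusted p = 0.0336). The other regulators were not called, with log2 fold changes of -0.06, adjusted p = 0.557 for Myf5, -0.10, adjusted p = 0.786 for Myog, and 0.10, adjusted p = 0.402 for Pax7, the satellite cell transcription factor gene. Myog turned to 0.05 without Jmjd3 KO replicate 2 and to 0.13 without Tdt control replicate 1. In the quiescence-associated list, the cell cycle inhibitor gene Cdkn1b (0.34, adjusted p = 0.0118) and the growth factor receptor gene Fgfr4 (0.50, adjusted p = 0.0158) rose among 30 genes (2 adjusted over the list alone; camera adjusted p = 0.172). Myom2, Mef2c, Atp2a1, Cdkn1b and Fgfr4 lost their calls without Jmjd3 KO replicate 1 (adjusted p from 0.0793 to 0.205). Myom2, Mef2c, Atp2a1, Ryr1, Cdkn1b and Fgfr4 were no longer called without Jmjd3 KO replicate 2 and without Tdt control replicate 1 (adjusted p from 0.0589 to 0.199). Myom2, Mef2c, Cdkn1b and Fgfr4 fell out of the calls without Tdt control replicate 2 (adjusted p from 0.0594 to 0.0909). Myom2 lost the call without Utx KO replicate 2 (adjusted p = 0.0504). Myod1 was no longer called without each of the 6 libraries (adjusted p from 0.0539 to 0.209).

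In the hyaluronan list, 4 of 22 measured genes rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.525). Beside Has2, Cd44, the gene of a hyaluronan receptor, fell (-0.28, adjusted p = 0.0106), while Ugdh, which makes a sugar precursor of hyaluronan (0.45, adjusted p = 0.00739), and Ptx3, an inflammatory gene whose protein binds hyaluronan matrix (0.70 ± 0.08, adjusted p = 0.00469), rose. The extracellular matrix list held Tnc and Col4a2 (-0.32, adjusted p = 0.0270) as the genes that fell and Thbs1 (0.30, adjusted p = 0.0335) as the 1 that rose, of 38 (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.816). Cd44, Ugdh, Col4a2 and Thbs1 lost their calls without Jmjd3 KO replicate 1 (adjusted p from 0.0591 to 0.192). Cd44, Col4a2 and Thbs1 were no longer called without Jmjd3 KO replicate 2 and without Tdt control replicate 1 (adjusted p from 0.0588 to 0.121). Col4a2 and Thbs1 fell out of the calls without Tdt control replicate 2 (adjusted p from 0.0887 to 0.126).

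Of 33 measured NF-kB targets and cytokines, 12 rose and 1 fell in Jmjd3 KO (20 and 3 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 2.95e-08; adjusted p = 0.483 with an estimated correlation). The monocyte attractant gene Ccl2, on chromosome 11, changed by 0.67 ± 0.07, adjusted p = 0.00446, and the neutrophil attractant genes Cxcl5 and Cxcl1 by 0.66, adjusted p = 0.00522 and 0.58, adjusted p = 0.00942. Of 15 measured neutrophil markers, 6 rose (12 higher and 1 lower adjusted over the list alone; median 0.65; camera adjusted p = 5.99e-05, and adjusted p = 0.646 with an estimated correlation). They held Hdc at 1.12 ± 0.11, adjusted p = 0.00368, Mxd1 at 0.71 ± 0.07, adjusted p = 0.00369 and S100a9, a calcium-binding protein gene abundant in neutrophils, at 62.3 ± 11.3 against 32.3 ± 1.83 CPM (mean ± SD, n = 2). Of 25 macrophage and monocyte markers, Cd14 (0.72, adjusted p = 0.0206), Clec4d and Tyrobp rose (9 adjusted over the list alone; camera adjusted p = 0.0364; adjusted p = 0.767 with an estimated correlation). The macrophage and monocyte list lost the call without Tdt control replicate 1 (adjusted p = 0.900). Of 56 interferon-response genes, 6 rose (28 higher and 1 lower adjusted over the list alone; median 0.35; camera adjusted p = 5.82e-12; adjusted p = 0.583 with an estimated correlation). The largest of these changes was that of Xaf1, a gene of chromosome 11 (2.40 ± 0.14, adjusted p = 4.47e-04), and the antigen peptide transporter genes Tap2 and Tap1 rose by 0.67 ± 0.05 and 0.55 ± 0.09. Without chromosome 11, a test added after the data were seen, the interferon and NF-kB lists kept camera adjusted p of 1.12e-12 and 6.27e-07. Cxcl5, Cxcl1, S100a9, Cd14, Clec4d and Tap1 lost their calls without Jmjd3 KO replicate 1 (adjusted p from 0.0570 to 0.139). Tap1 was no longer called without Jmjd3 KO replicate 2 (adjusted p = 0.0978). Cxcl1, S100a9, Cd14 and Clec4d fell out of the calls without Tdt control replicate 1 (adjusted p from 0.0647 to 0.156). S100a9, Cd14, Clec4d and Tap1 lost their calls without Tdt control replicate 2 (adjusted p from 0.0667 to 0.106). Clec4d was no longer called without Utx KO replicate 1 and without Utx KO replicate 2 (adjusted p from 0.0664 to 0.0671). Tyrobp fell out of the calls without each of the 6 libraries (adjusted p from 0.0530 to 0.242).

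In Jmjd3 KO the ribosome biogenesis list had a median of -0.14 over 45 genes, of which Wdr43 (-0.23, adjusted p = 0.0392) and Heatr1 (-0.20, adjusted p = 0.0493) fell (14 adjusted over the list alone; camera adjusted p = 1.26e-09; adjusted p = 0.483 with an estimated correlation). DNA replication genes had a median of -0.14 over 44 genes, none called by edgeR over all genes tested, 3 lower adjusted over the list alone and 23 lower at an unadjusted p under 0.05 (camera adjusted p = 1.60e-08; adjusted p = 0.560 with an estimated correlation). Cholesterol synthesis genes had a median of -0.09 (camera adjusted p = 0.0411; adjusted p = 0.767 with an estimated correlation), with 0 of 25 called by edgeR over all genes tested, 5 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. Among p53 targets, Gdf15, a stress-induced secreted factor gene (1.29, adjusted p = 0.0366), rose (4 of 30 adjusted over the list alone; camera adjusted p = 0.00524; adjusted p = 0.483 with an estimated correlation). Hox genes had a median of 0.26, with Hoxc10 (0.26, adjusted p = 0.0431) the 1 of 23 that rose, also adjusted over the list alone (camera adjusted p = 0.00624; adjusted p = 0.634 with an estimated correlation). In glycolysis, the lactate transporter gene Slc16a3 rose (0.70 ± 0.07, adjusted p = 0.00446; 3 of 21 adjusted over the list alone; camera adjusted p = 0.0407; adjusted p = 0.651 with an estimated correlation). The list's call ended without chromosome 11, on which Slc16a3 lies (adjusted p = 0.0938). The glycolysis list and Gdf15 lost their calls without Jmjd3 KO replicate 1 and without Tdt control replicate 1 (adjusted p from 0.0640 to 0.122). The glycolysis list, the cholesterol synthesis list and Gdf15 were no longer called without Jmjd3 KO replicate 2 and without Tdt control replicate 2 (adjusted p from 0.0549 to 0.833). Wdr43, Heatr1 and Hoxc10 fell out of the calls without each of the 6 libraries (adjusted p from 0.0610 to 0.296).

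The lists that camera did not call in Jmjd3 KO had adjusted p of 0.0679 to 0.973. Among immediate early genes, 5 of 41 rose, with Ier3 at 0.83 ± 0.06, adjusted p = 9.16e-04, and Fosl1, a subunit of the AP-1 transcription factor, fell (-0.70 ± 0.07, adjusted p = 0.00340; 7 higher and 7 lower adjusted over the list alone). Among regulators of the histone site that JMJD3 acts on, Epop, which encodes a PRC2-associated protein and lies on chromosome 11, fell with Kdm6b (-0.64 ± 0.06, adjusted p = 0.00327; 3 of 25 lower adjusted over the list alone). In the TGF-beta and BMP list Id1 (-0.41, adjusted p = 0.0122) was among 2 that fell and Tgfb3 (0.39, adjusted p = 0.0493) rose, of 31 (5 and 5 adjusted over the list alone). In the unfolded protein list Asns (-0.34, adjusted p = 0.0269) fell and Herpud1 (0.29, adjusted p = 0.0317) rose, of 28 (1 and 1 adjusted over the list alone). In the Schwann cell list Pmp22 (0.30, adjusted p = 0.0454), on chromosome 11, rose (1 of 11 adjusted over the list alone). The Notch list had no call over all genes tested (4 higher and 1 lower of 23 adjusted over the list alone, 8 and 3 at an unadjusted p under 0.05). No edgeR call over all genes or over the list alone was made in the G2 and mitosis, respiratory chain, fibro-adipogenic, endothelial, tenocyte, erythroid and sex-linked lists (1, 0, 5, 1, 2, 0 and 1 members at an unadjusted p under 0.05). Mural markers had 1 of 14 lower and lymphoid markers 1 of 2 higher, both adjusted over the list alone, and 0 called over all genes (2 and 1 at an unadjusted p under 0.05). Median, mean and test differed in sign for the G2 and mitosis list (0.0028, 0.0146, down), the respiratory chain (-0.0046, 0.0013, down), TGF-beta and BMP (0.0065, -0.0064, down) and the histone site regulators (-0.02, 0.05, down). Id1, Asns, Herpud1 and Pmp22 lost their calls without Jmjd3 KO replicate 1, without Jmjd3 KO replicate 2 and without Tdt control replicate 1 (adjusted p from 0.0647 to 0.219). Asns and Herpud1 were no longer called without Tdt control replicate 2 (adjusted p from 0.0793 to 0.0942). Pmp22 fell out of the calls without Utx KO replicate 1 and without Utx KO replicate 2 (adjusted p from 0.0725 to 0.0772). Tgfb3 lost the call without each of the 6 libraries (adjusted p from 0.0593 to 0.266).

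The genes called in Jmjd3 KO were unevenly spread over the chromosomes, a feature chosen after the values were seen. On chromosome 11, which carries Kdm6b, 104 of 1284 tested genes (8.10%) changed, against 409 of 15800 (2.59%) elsewhere (odds ratio 3.32, 95% interval 2.63 to 4.16; 2-sided Fisher's exact test, p = 3.45e-21, genes counted as independent). Within 40 Mb of Kdm6b 92 of 931 genes (9.88%) were called, and 12 of 353 (3.40%) on the rest of the chromosome. In Utx KO 17 of 1284 genes (1.32%) of chromosome 11 were called, and 276 of 15800 (1.75%) elsewhere (odds ratio 0.755, 0.432 to 1.24). Left without chromosome 11, a count added after the data were seen, Jmjd3 KO had 349 changed genes.

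**Figure D2:**
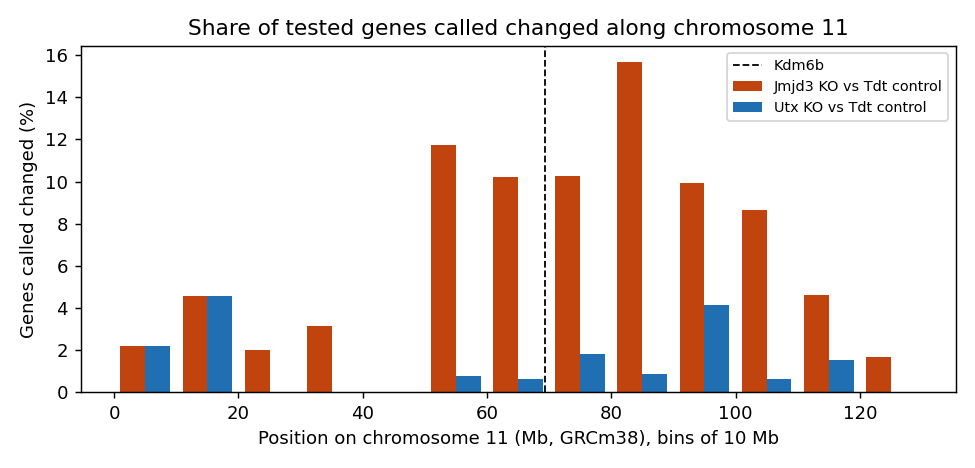
Share of tested genes called changed (y axis, percent) in bins of 10 Mb along chromosome 11 (x axis, Mb in GRCm38) in Jmjd3 KO (orange bars) and Utx KO (blue bars) against Tdt control; the dashed line marks Kdm6b. In Jmjd3 KO the share is 8.64% to 15.7% in the 6 bins from 50 to 110 Mb, and in Utx KO it is at most 4.13% in every bin except 10 to 20 Mb (4.55%, 1 of 22 genes).

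Utx KO was compared with the same controls to ask what differs without UTX. Myf5 and Myog, genes of an early and a late myogenic transcription factor, rose from 61.2 ± 1.32 to 83.1 ± 0.776 and from 6.87 ± 1.40 to 13.6 ± 0.979 CPM (mean ± SD, n = 2), while Myod1 fell from 471 ± 2.91 to 405 ± 3.15. Adm, which encodes the peptide adrenomedullin, rose 2.28-fold to 23.3 ± 0.827 CPM, and Cdkn1c, an imprinted cell cycle inhibitor gene, rose 2.02-fold to 9.04 ± 2.39. Kbtbd12 (ENSMUSG00000033182.12, chromosome 6, 88545114 to 88637950) fell 7.43-fold, from 12.8 ± 0.217 to 1.73 ± 0.135 CPM, and the lipase gene Mgll 2.40-fold. Both lie from 80 to 90 Mb on chromosome 6, a stretch picked after the values were seen. There 12 of 119 genes (10.1%) were called in Utx KO, against 1.72% over all genes tested. By camera at its fixed correlation the unfolded protein response list was higher. The interferon-response, macrophage, mural and endothelial lists were lower. None of them was called with an estimated correlation (adjusted p = 0.483, 0.646, 0.634, 0.483 and 0.634, in that order). Summed CPM of interferon-response genes were 605.8 and 604.0 in Utx KO, against 640.8 and 601.2 in Tdt control. Those of macrophage markers were 281.0 and 321.2, against 320.9 and 378.9, so the groups overlapped in both sums. The mural and endothelial sums were lower in both Utx KO libraries than in both controls.

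In all, 293 of 17084 genes changed in Utx KO (135 higher, 158 lower), 48 of them by at least 2-fold. By the same rule, which 117 higher and 120 lower genes passed, the 10 largest increases were Adm (1.19 ± 0.07, adjusted p = 0.00140), Cdkn1c (1.01, adjusted p = 0.0396), Myog (0.98, adjusted p = 0.0309), Cdc42bpa, Cd200, Ccng2, Hdc, Prelp, Kcns3 and Hmox1, the last with 0.75, adjusted p = 0.0407. The 10 largest decreases were Kbtbd12 (-2.89 ± 0.09, adjusted p = 1.63e-05), Kdm6a, Sbsn (-1.42, adjusted p = 0.00939), Chil3, Mgll (-1.26 ± 0.07, adjusted p = 5.48e-04), Nwd1, Susd5, Thy1, Arnt2 and Olfml2a, the last with -0.92, adjusted p = 0.0264. Beside these, Myf5 (ENSMUSG00000000435.1, chromosome 10, 107482908 to 107486134) had 0.44 ± 0.05, adjusted p = 0.0153, Myod1 -0.22 ± 0.04, adjusted p = 0.0461, Has2 0.20 ± 0.09, adjusted p = 0.335 and Pax7 0.02 ± 0.06, adjusted p = 0.879. The count was 96 without Jmjd3 KO replicate 1, 92 without Jmjd3 KO replicate 2, 16 without Tdt control replicate 1 and 55 without Tdt control replicate 2. It was 20 without Utx KO replicate 1 and 71 without Utx KO replicate 2, and 119 with only the 4 libraries compared. With transcript length offsets Myod1, Hmox1, Arnt2, Fgfr4, Cav1, Chrnd, Tnnt3, Cemip2, Col18a1, Fbln2, Bgn, Stat2, Ccl7, Hk2, Bmp4, Epop, Ctss, Fcgr1, Mcam, Myl9 and Chodl were not called (adjusted p from 0.0521 to 0.186). Cdkn1c and Hmox1 lost their calls without Jmjd3 KO replicate 1 and without Jmjd3 KO replicate 2 (adjusted p from 0.0796 to 0.0900). Cdkn1c, Cdc42bpa, Ccng2, Hdc, Prelp, Hmox1, Nwd1, Susd5, Thy1, Arnt2, Olfml2a and Myf5 were no longer called without Tdt control replicate 1 (adjusted p from 0.0509 to 0.133). Cdkn1c, Ccng2, Hdc, Hmox1, Nwd1, Thy1, Olfml2a and Myf5 fell out of the calls without Tdt control replicate 2 (adjusted p from 0.0501 to 0.141). Cd200, Ccng2, Hdc, Prelp, Hmox1, Sbsn, Chil3, Susd5, Thy1, Arnt2, Olfml2a and Myf5 lost their calls without Utx KO replicate 1 (adjusted p from 0.0531 to 0.170). Cdkn1c, Ccng2, Hdc, Prelp, Susd5, Thy1, Arnt2 and Myf5 were no longer called without Utx KO replicate 2 (adjusted p from 0.0512 to 0.0918). Myog, Myod1 and Kcns3 fell out of the calls without each of the 6 libraries (adjusted p from 0.0504 to 0.199).

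Of 28 measured genes of the unfolded protein response, 6 rose in Utx KO (11 adjusted over the list alone; median 0.13; camera adjusted p = 1.92e-04; adjusted p = 0.483 with an estimated correlation), among them the chaperone genes Hsp90b1 (0.38 ± 0.04, adjusted p = 0.0118) and Hspa5 (0.26 ± 0.04, adjusted p = 0.0267). In the quiescence-associated list Cdkn1b (0.36, adjusted p = 0.0182), Fgfr4 (0.48, adjusted p = 0.0279), Cav1 (0.27, adjusted p = 0.0350) and Cdkn1c rose, of 30 (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00358; adjusted p = 0.597 with an estimated correlation). In the muscle differentiation list Myog rose and the acetylcholine receptor subunit gene Chrnd (-0.61, adjusted p = 0.0382) fell, of 32 (2 and 1 adjusted over the list alone; camera adjusted p = 0.768). Among mature fibre genes the troponin gene Tnnt3 (-0.33, adjusted p = 0.0463) fell, 1 of 26 also adjusted over the list alone (camera adjusted p = 0.415). The glycolysis list had 1 call, the hexokinase gene Hk2 (0.32, adjusted p = 0.0366). The list had 4 higher and 1 lower of 21 adjusted over the list alone (camera adjusted p = 0.0230; adjusted p = 0.646 with an estimated correlation). The Hox list had a median of 0.18 (0 calls by edgeR over all genes tested, 4 of 23 at an unadjusted p under 0.05, 2 adjusted over the list alone; camera adjusted p = 0.0232; adjusted p = 0.634 with an estimated correlation). The cholesterol synthesis list had a median of 0.08 (0 calls, 3 of 25 at an unadjusted p under 0.05, 1 adjusted over the list alone; camera adjusted p = 0.0313; adjusted p = 0.767 with an estimated correlation). Ribosome biogenesis genes had a median of -0.06 (0 calls, 1 higher and 8 lower of 45 at an unadjusted p under 0.05, 0 adjusted over the list alone; camera adjusted p = 0.0230; adjusted p = 0.646 with an estimated correlation). The ribosome biogenesis list, Fgfr4 and Cdkn1c lost their calls without Jmjd3 KO replicate 1 (adjusted p from 0.0622 to 0.0837). The ribosome biogenesis list, Hspa5, Fgfr4 and Cdkn1c were no longer called without Jmjd3 KO replicate 2 (adjusted p from 0.0524 to 0.0796). The quiescence-associated list, the ribosome biogenesis list, the cholesterol synthesis list, Hsp90b1, Hspa5, Fgfr4 and Cdkn1c fell out of the calls without Tdt control replicate 1 (adjusted p from 0.0602 to 0.965). The glycolysis list, the Hox list, Hspa5, Fgfr4 and Cdkn1c lost their calls without Tdt control replicate 2 (adjusted p from 0.0671 to 0.141). The Hox list, the cholesterol synthesis list, Hsp90b1, Hspa5 and Fgfr4 were no longer called without Utx KO replicate 1 (adjusted p from 0.0912 to 0.338). The ribosome biogenesis list, the glycolysis list, Hspa5 and Cdkn1c fell out of the calls without Utx KO replicate 2 (adjusted p from 0.0912 to 0.344). Cdkn1b, Cav1, Myog, Chrnd, Tnnt3 and Hk2 lost their calls without each of the 6 libraries (adjusted p from 0.0504 to 0.225).

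Of 56 interferon-response genes in Utx KO, the immunity GTPase gene Iigp1 (-1.72 ± 0.19, adjusted p = 0.0131) and the antigen presentation gene B2m (-0.51 ± 0.08, adjusted p = 0.0279) fell and Stat2, which carries interferon signals, rose (1.23 ± 0.16, adjusted p = 0.0182; 6 lower and 1 higher adjusted over the list alone; median -0.17; camera adjusted p = 8.41e-05; adjusted p = 0.646 with an estimated correlation). Of 25 macrophage and monocyte markers Chil3 (-1.30, adjusted p = 0.0111), Ctss (-0.53, adjusted p = 0.0391) and Fcgr1 (-0.79, adjusted p = 0.0430) fell (15 lower and 1 higher adjusted over the list alone; median -0.41; camera adjusted p = 7.54e-07; adjusted p = 0.634 with an estimated correlation). Of 14 mural cell markers Mcam (-0.57, adjusted p = 0.0264) and Myl9 (-0.89, adjusted p = 0.0382) fell (9 adjusted over the list alone; median -0.50; camera adjusted p = 1.85e-06; adjusted p = 0.483 with an estimated correlation). Endothelial markers had a median of -0.40, with 0 of 20 called by edgeR over all genes tested, 9 lower at an unadjusted p under 0.05 and 5 adjusted over the list alone (camera adjusted p = 6.95e-06; adjusted p = 0.634 with an estimated correlation). Among fibro-adipogenic markers Thy1 (-1.02, adjusted p = 0.0213) fell, of 20 (1 higher and 1 lower adjusted over the list alone; median -0.25; camera adjusted p = 0.00302; adjusted p = 0.646 with an estimated correlation). In the matrix list Col18a1 (-0.39, adjusted p = 0.0293), Fbln2 (-0.40, adjusted p = 0.0412) and Bgn (-0.43, adjusted p = 0.0415) fell (11 of 38 adjusted over the list alone; camera adjusted p = 0.0230; adjusted p = 0.767 with an estimated correlation). Neutrophil markers went the other way, with a median of 0.32, Hdc (0.79, adjusted p = 0.0239) as the 1 of 15 called, and 8 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0232; adjusted p = 0.766 with an estimated correlation). Myl9 lost the call without Jmjd3 KO replicate 1 and without Jmjd3 KO replicate 2 (adjusted p from 0.0721 to 0.0758). The extracellular matrix list, the neutrophil list, Iigp1, Stat2, Thy1, Hdc and Myl9 were no longer called without Tdt control replicate 1 (adjusted p from 0.0607 to 0.275). Stat2, Thy1 and Hdc fell out of the calls without Tdt control replicate 2 (adjusted p from 0.0696 to 0.0860). The extracellular matrix list, the fibro-adipogenic list, Iigp1, Chil3, Thy1, Hdc and Myl9 lost their calls without Utx KO replicate 1 (adjusted p from 0.0591 to 0.748). The neutrophil list, Iigp1, Stat2, Thy1, Hdc and Myl9 were no longer called without Utx KO replicate 2 (adjusted p from 0.0551 to 0.0912). B2m, Ctss, Fcgr1, Mcam, Col18a1, Fbln2 and Bgn fell out of the calls without each of the 6 libraries (adjusted p from 0.0509 to 0.215).

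The remaining lists were not called by camera in Utx KO, with adjusted p of 0.201 to 0.994. Among immediate early genes Hsph1 (0.44, adjusted p = 0.0179) and Ier3 (0.39, adjusted p = 0.0283) were among 3 that rose and Klf2 (-0.43, adjusted p = 0.0176) and Fosb (-0.48, adjusted p = 0.0288) among 3 that fell, of 41 (6 and 7 adjusted over the list alone). In the NF-kB list Cxcl1 (0.54, adjusted p = 0.0213) rose and Ccl7 (-0.52, adjusted p = 0.0463) fell, of 33 (4 and 5 adjusted over the list alone). Among TGF-beta and BMP genes Bmp4 (0.37, adjusted p = 0.0288) rose and Id1 (-0.48, adjusted p = 0.0151) fell, of 31 (2 and 2 adjusted over the list alone). The hyaluronidase gene Cemip2 (-0.29, adjusted p = 0.0309) fell in the hyaluronan list (2 higher and 2 lower of 22 adjusted over the list alone). Epop (0.39, adjusted p = 0.0283) rose among the histone site regulators as Kdm6a fell (4 and 1 of 25 adjusted over the list alone). Chodl (0.49, adjusted p = 0.0445) rose in the tenocyte list (1 of 8 adjusted over the list alone). The p53 list had 1 higher and 3 lower of 30, and the Notch list 2 higher and 3 lower of 23, adjusted over the list alone (2 higher and 4 lower at an unadjusted p under 0.05 in each), and the sex-linked list 1 lower of 6 adjusted over the list alone (2 higher and 1 lower unadjusted), with 0 called over all genes in these lists. No edgeR call over all genes or over the list alone was made among DNA replication, G2 and mitosis, respiratory chain, lymphoid, Schwann cell and erythroid genes (2, 3, 4, 0, 1 and 1 members at an unadjusted p under 0.05). Median, mean and test differed in sign for muscle differentiation (-0.03, 0.0024, down), TGF-beta and BMP (-0.0002, 0.0131, up) and the histone site regulators (-0.02, 0.02, up). Chodl lost the call without Jmjd3 KO replicate 1 and without Jmjd3 KO replicate 2 (adjusted p = 0.102). Hsph1, Fosb, Cxcl1, Id1 and Chodl were no longer called without Tdt control replicate 1, without Utx KO replicate 1 and without Utx KO replicate 2 (adjusted p from 0.0531 to 0.197). Hsph1, Fosb and Cxcl1 fell out of the calls without Tdt control replicate 2 (adjusted p from 0.0775 to 0.0795). Ier3, Klf2, Ccl7, Bmp4, Cemip2 and Epop lost their calls without each of the 6 libraries (adjusted p from 0.0515 to 0.230).

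**Figure D3:**
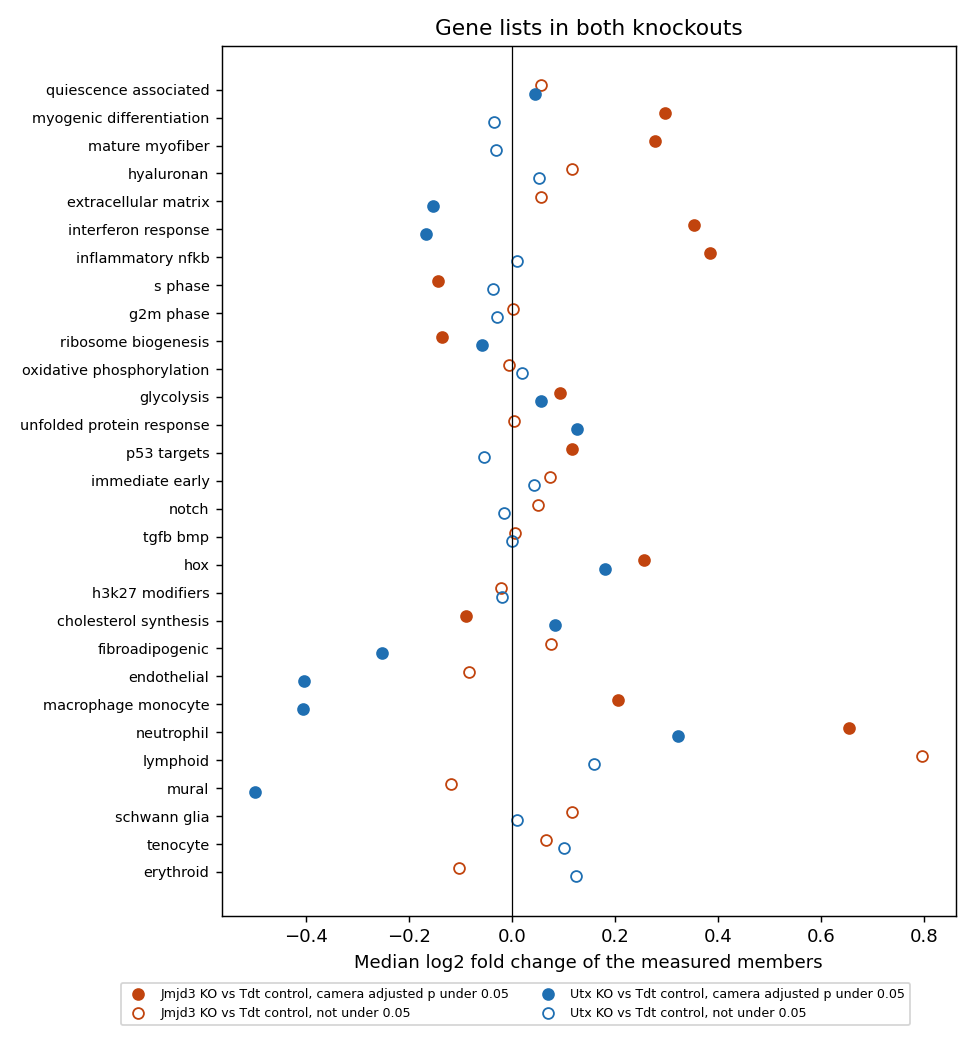
Median log2 fold change (x axis) of the measured members of each gene list (y axis, the sex-linked list left out) in Jmjd3 KO (orange) and Utx KO (blue) against Tdt control; filled points had a camera adjusted p under 0.05 at the fixed correlation. With an estimated correlation camera called 0 lists in either comparison (lowest adjusted p = 0.483; 3 and 2 at an unadjusted p under 0.05). The interferon-response list lies at 0.35 in Jmjd3 KO and -0.17 in Utx KO, and the macrophage list at 0.21 and -0.41.

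Jmjd3 KO was compared directly with Utx KO, the test of whether the effects of the knockouts differ. Has2 was lower in Jmjd3 KO (9.35 ± 1.27 CPM against 26.2 ± 0.608, mean ± SD, n = 2; log2 fold change -1.49 ± 0.10, adjusted p = 3.14e-04), as were Hmga2 (-1.41 ± 0.10, adjusted p = 4.25e-04), Sox11 (-1.28 ± 0.05, adjusted p = 4.43e-05) and Dlk1 (-1.55 ± 0.09, adjusted p = 2.40e-04). Myog was also lower (-1.08 ± 0.16, adjusted p = 0.00922), while the fibre gene Myh4 (0.86 ± 0.09, adjusted p = 0.00308) and Des (0.38 ± 0.04, adjusted p = 0.00211) were higher. Interferon-response genes such as B2m (0.75 ± 0.08, adjusted p = 0.00276) and Iigp1 (1.72 ± 0.19, adjusted p = 0.00350), and the macrophage marker Ctss (0.81 ± 0.09, adjusted p = 0.00385), were higher in Jmjd3 KO.

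This comparison called 1370 of 17084 genes (877 higher and 493 lower in Jmjd3 KO), 219 of them by at least 2-fold. The 10 genes that were highest in Jmjd3 KO by the naming rule, which 627 higher and 387 lower genes passed, were Kbtbd12 (3.15 ± 0.09, adjusted p = 5.75e-06), AA465934, Kdm6a (2.06 ± 0.06, adjusted p = 5.75e-06), Susd5, Olfml2a, Sod3, Sbsn, Smtnl2, Mgll and Lpl, the last with 1.16 ± 0.08, adjusted p = 3.46e-04. Those lowest were Esm1 (-1.65 ± 0.16, adjusted p = 0.00199), Dlk1, Zfp651, Has2, Adm, Slfn9, Hmga2, Hebp1, Arl4d and Sox11. Of these, AA465934, Smtnl2, Slfn9 and Arl4d lie on chromosome 11, where 186 of 1284 genes (14.5%) were called against 7.49% elsewhere. The count was 345 without Jmjd3 KO replicate 1, 334 without Jmjd3 KO replicate 2, 291 without Utx KO replicate 1 and 679 without Utx KO replicate 2. With transcript length offsets Zfp651, Hebp1, Mxd1, Csf3r, Kdm5d and Ddx3y were not called (adjusted p from 0.0587 to 0.344). Smtnl2 lost the call without Jmjd3 KO replicate 1 (adjusted p = 0.0651). Smtnl2 and Myog were no longer called without Jmjd3 KO replicate 2 (adjusted p from 0.0540 to 0.0584). Zfp651 fell out of the calls without Tdt control replicate 1 and without Utx KO replicate 2 (adjusted p from 0.0523 to 0.128). Sod3, Zfp651, Hebp1 and Myog lost their calls without Utx KO replicate 1 (adjusted p from 0.0521 to 0.104).

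By camera at its fixed correlation, interferon-response genes (28 of 56 higher and 1 lower, 40 and 3 adjusted over the list alone; median 0.69; camera adjusted p = 1.74e-15) and macrophage markers (15 of 25 higher, 19 adjusted over the list alone; median 0.58; camera adjusted p = 1.36e-09) were higher in Jmjd3 KO than in Utx KO. The adjusted p with an estimated correlation were 0.560 and 0.634 for these lists. NF-kB genes had 17 of 33 higher and 1 lower (17 and 2 adjusted over the list alone), with Ccl2 at 0.93 ± 0.07, adjusted p = 7.17e-04 and Lif at 0.65 ± 0.08, adjusted p = 0.00430, both on chromosome 11 (camera adjusted p = 5.58e-06; adjusted p = 0.483 with an estimated correlation). Neutrophil markers had 3 higher of 15, also adjusted over the list alone, namely Trem1 (0.69, adjusted p = 0.00820), Mxd1 and Csf3r (camera adjusted p = 0.0162; adjusted p = 0.755 with an estimated correlation). Mature fibre genes had 11 of 26 higher (17 adjusted over the list alone; camera adjusted p = 1.88e-06; adjusted p = 0.646 with an estimated correlation). Muscle differentiation genes had 6 of 32 higher and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.00127; adjusted p = 0.646 with an estimated correlation). Unfolded protein response genes had 1 of 28 higher and 10 lower (3 and 12 adjusted over the list alone), with Asns at -0.56 ± 0.06, adjusted p = 0.00300 and Hsp90b1 at -0.32 ± 0.04, adjusted p = 0.00556 (camera adjusted p = 0.00301; adjusted p = 0.483 with an estimated correlation). Among p53 targets 5 of 30 were higher and 1 lower (6 and 1 adjusted over the list alone), with Ephx1 at 0.87 ± 0.11, adjusted p = 0.00554 (camera adjusted p = 0.00226; adjusted p = 0.483 with an estimated correlation). The fibro-adipogenic (4 of 20 higher), endothelial (2 of 20) and mural (2 of 14) lists had camera adjusted p of 0.00224, 0.00391 and 0.00398, with 4, 5 and 4 higher adjusted over the list alone and, in the endothelial list, 1 lower. With an estimated correlation these were not called (adjusted p = 0.646, 0.667 and 0.583, in that order). DNA replication (2 of 44 lower, 1 adjusted over the list alone), ribosome biogenesis (2 of 45 lower, 0 adjusted over the list alone) and cholesterol synthesis (1 of 25 lower, also adjusted over the list alone) had camera adjusted p of 1.92e-04, 3.82e-04 and 3.69e-04 (adjusted p = 0.634, 0.634 and 0.646 with an estimated correlation). The neutrophil list, Mxd1 and Csf3r lost their calls without Jmjd3 KO replicate 1 (adjusted p from 0.110 to 0.304). The endothelial list was no longer called without Jmjd3 KO replicate 2 (adjusted p = 0.189). Csf3r fell out of the calls without Tdt control replicate 1 and without Tdt control replicate 2 (adjusted p from 0.0613 to 0.0630). The fibro-adipogenic list, the neutrophil list, Trem1, Mxd1 and Csf3r lost their calls without Utx KO replicate 1 (adjusted p from 0.0602 to 0.191). The endothelial list, Mxd1 and Csf3r were no longer called without Utx KO replicate 2 (adjusted p from 0.0569 to 0.131).

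In the other lists of the direct comparison, camera adjusted p ran from 0.0605, for the matrix list with 11 of 38 genes higher and 4 lower (16 and 4 adjusted over the list alone), to 0.988. Among immediate early genes 8 of 41 were higher and 4 lower (15 and 5 adjusted over the list alone), in the quiescence-associated list 1 and 3 of 30 (3 and 7), and in the hyaluronan list 3 and 3 of 22 (5 and 3). The second pairs, here and next, are adjusted over the list alone. The counts were, in the glycolysis list 2 and 2 of 21 (2 and 2), in the Notch list 2 and 1 of 23 (4 and 2), in the TGF-beta and BMP list 1 and 1 of 31 (1 and 1), and among the histone site regulators 2 and 4 of 25 (2 and 6). The Schwann cell list had 1 higher of 11, the tenocyte list 1 lower of 8, and the sex-linked list 3 lower of 6 (Uty, Kdm5d and Ddx3y), with the same counts adjusted over the list alone except for 2 more, higher, in the sex-linked list. No edgeR call over all genes tested was made in the G2 and mitosis, respiratory chain, Hox, lymphoid and erythroid lists (4, 5, 1, 1 and 3 members at an unadjusted p under 0.05; 0, 0, 0, 1 and 3 adjusted over the list alone). Median, mean and test differed in sign for the histone site regulators (-0.0051, 0.03, down), tenocyte (-0.04, 0.11, down) and sex-linked lists (-0.21, 0.85, down). Epop (-1.03 ± 0.06, adjusted p = 2.40e-04) was among the regulators that were lower in Jmjd3 KO.

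Some genes changed the same way in both knockouts. Both raised Cdc42bpa (0.93 ± 0.09 in Jmjd3 KO and 0.93 ± 0.09 in Utx KO, SE), Hdc, the growth factor receptor gene Fgfr4, the cell cycle inhibitor gene Cdkn1b and the stress gene Ddit4 (0.70 ± 0.07 and 0.63 ± 0.07). They lowered Myod1 and the histone gene Hist1h2bj (-0.29 ± 0.05 and -0.45 ± 0.05). Ddit4, Hist1h2bj and, below, Igf2 and Ifitm3 were picked after their values were seen, and their single calls were not followed with each library left out. Together 48 genes were called in the same direction (29 higher, 19 lower), where independent lists would share 4.29. Simulated unchanged groups that share the controls gave a mean of 0.92 and at most 3 in 50 draws. Those groups held no changed genes, so few shared calls were possible in them. Neither value shows how many of the 48 the shared controls account for. Another 11 were called in opposite directions, among them Igf2, a growth factor gene (-0.47 ± 0.09 and 0.60 ± 0.09), Susd5, Epop and Ifitm3. Across genes the log2 fold changes had a correlation of 0.34, against a mean of 0.48 in the simulated groups, and a covariance of 0.110 against 0.0545. Both comparisons use the same 2 control libraries, which cannot be divided between them. The counts of 48 and 11 were 6 and 2 without Jmjd3 KO replicate 1, 17 and 1 without Jmjd3 KO replicate 2, and 12 and 3 without Utx KO replicate 2. They were 2 and 0 without Tdt control replicate 1, 14 and 0 without Tdt control replicate 2, and 2 and 0 without Utx KO replicate 1.

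The authors' deposited tables of the knockout comparisons held 876 genes with an adjusted p under 0.05 in Jmjd3 KO (530 higher, 346 lower) and 629 in Utx KO (296 higher, 333 lower). Of the genes called here, 445 of 513 and 267 of 293 were also called there, each in the same direction. In those tables Kdm6b had an adjusted p of 5.76e-06 in Jmjd3 KO, Kdm6a 1.09e-04 in Utx KO, Has2 3.23e-21 in Jmjd3 KO, and Hebp1 0.211 in Jmjd3 KO.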

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

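Chosen after the data were seen were the tests without chromosome 11 and without genes of other cell types. The 513, 293 and 1370 genes changed in Jmjd3 KO, in Utx KO and between the knockouts became 1872, 1399 and 2856 without a low-count filter and 331, 131 and 793 with transcript length offsets. A replicate block gave 322 and 133 in the knockouts, DESeq2 1041 and 658, and the 4 libraries compared alone 119 in Utx KO. With each library left out the counts ran from 113 to 434, 16 to 96 and 291 to 1387, fits with fewer libraries, and otherwise the cause was not tested. Of these counts under all settings, 26 lay within 1.5 times the values reported, among them 349, 289 and 1114 without chromosome 11 and 485, 284 and 1307 without genes of other cell types. Deviations of libraries from their group mean (log2 CPM) had, between groups for the same replicate number, correlations across genes of -0.0107, -0.00813 and -0.0532.

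Kdm6b in Jmjd3 KO ran from -0.87 to -0.49 with a library left out, its call ending without Jmjd3 KO replicate 1 (adjusted p = 0.167) and without Jmjd3 KO replicate 2 (adjusted p = 0.123). Kdm6a in Utx KO ran from -2.18 to -2.12. The 12, 13 and 14 lists called became 0, 0 and 0 with an estimated correlation (camera; 3, 2 and 3 at an unadjusted p under 0.05) and 3, 2 and 4 with fry, and ran from 11 to 14, 10 to 13 and 13 to 15 with a library left out. The 48 genes called alike in both knockouts became 131 at an adjusted p under 0.1, 24 with a replicate block, 137 with DESeq2, and 2 to 17 with a library left out. The 11 called in opposite directions became 39, 3, 39 and 0 to 3 under the same settings, and 7 without chromosome 11. The cause was not tested.

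Of the named genes' other values, 3880 kept direction and side of the threshold, 694 lost and 127 gained a call. Of those lost, 59 were lost with transcript length offsets, 50 with a replicate block and 36 with only the 4 libraries compared. Reversed, with the cause not tested, were Myog in Jmjd3 KO (0.05 without Jmjd3 KO replicate 2, 0.13 without Tdt control replicate 1, in a range from -0.28 to 0.13 with a library left out), Kdm6a in Jmjd3 KO (0.11 with transcript length offsets) and Pax7 in Utx KO (-0.0298 without Utx KO replicate 2, in a range from -0.0298 to 0.0778). Of the list medians' values, 328 kept their call and 101 lost it.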

Other observations

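All tests of this part were chosen after the results they measure were seen. Of 66 measured histone genes, a set also picked after its values were seen and put to no list test, 11 fell and 2 rose in Jmjd3 KO, and 8 fell in Utx KO. Both comparisons use the same 2 controls, whose histone shares of reads (1.94% and 1.91%) were above those of Jmjd3 KO (1.73% and 1.78%) and Utx KO (1.64% and 1.72%). Of 17 measured imprinted genes, picked in the same way and put to no list test, 6 were called in Utx KO (11 not) and 2 in Jmjd3 KO (15 not). Beside Cdkn1c, H19 (0.59 ± 0.06, adjusted p = 0.00941), Igf2 (0.60 ± 0.09, adjusted p = 0.0283), Peg10 (0.39 ± 0.06, adjusted p = 0.0279), Grb10 (0.28 ± 0.04, adjusted p = 0.0299) and Rian (0.73 ± 0.12, adjusted p = 0.0309) rose in Utx KO, while Igf2 (-0.47 ± 0.09, adjusted p = 0.0429) and Dlk1 (-1.22 ± 0.09, adjusted p = 9.16e-04) fell in Jmjd3 KO. Apart from Dlk1, whose call held with each library left out, these single calls were not followed with a library left out. On chromosome 6, 9 of 44 genes from 130 to 140 Mb, the bin of Hist4h4 and Hebp1, were called in Jmjd3 KO. In Utx KO 12 of 119 were called from 80 to 90 Mb, the bin of Kbtbd12 and Mgll.

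The genes called in Jmjd3 KO clustered on chromosome 11 around Kdm6b. Higher power on that chromosome was argued against by Utx KO, where the share of calls on chromosome 11 was 0.758 times that elsewhere. JMJD3 loss acting on the neighbours of its own gene, expected to lower them, was argued against as the cause of most of these calls. Within 40 Mb of Kdm6b 41.3% (38 of 92) were lower (95% Wilson interval 31.8 to 51.5). For the lower calls alone it stays open. Their share within 40 Mb (4.08%) was 7.20 times that on the rest of the chromosome (0.567%, 2 genes), and that of the higher calls 2.05 times, values that also restate the clustering. A flanking segment of another strain carried with the Jmjd3 allele stays open. The share called within 40 Mb was 2.91 times that on the rest of the chromosome, a value that restates the clustering and lends this explanation no support. The sequences that would show such a segment are not in the files used.

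Processed pseudogenes had large changes in Jmjd3 KO, where 25 of 799 were called, 23 of them higher, and they made up 23 of the 45 calls of at least 4-fold. A parent gene's change passed on in proportion to its pseudogene was argued against. With a parent counted once for each of its pseudogenes, the parents' median absolute log2 fold change was 0.25, against 5.95 for the pseudogenes. Phgdh, the parent of 8 of the pseudogenes, had -0.46 ± 0.08, adjusted p = 0.0285. Other misassignment of parent reads could not be decided, since a small share of a parent's reads could move with little change in the parent. A sequence or copy difference between the mice could not be decided by the floor and cut used, both set after the data were seen. At most 3 reads in each library of 1 group were found for 48.0% (12 of 25), just under the 50% set as the share it needs. Some of the others lay not far above that floor in Tdt control, such as Gm9347 (at most 585 reads in Jmjd3 KO and 5 in Tdt control) and Gm7901 (1251 and 22). Others were abundant in both groups, such as Gm1821 (13018 and 12567) and Gm48368 (978 and 667). None of the 25 lies on chromosome 11 itself. Where their parent genes lie was not examined, so a link of these calls to chromosome 11 was not excluded. Of all 799 tested, 7 were called in Utx KO, against 293 of 17084 (1.72%) over all genes tested.

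The macrophage, mural and endothelial lists were lower in Utx KO by camera at its fixed correlation, and none was called with an estimated correlation (adjusted p = 0.634, 0.483 and 0.634). Neither a lower share of every other cell type nor fewer cells of these types in the sort could be decided. Neutrophil markers had a median log2 fold change of 0.32, but they went both ways (8 higher and 3 lower adjusted over the list alone), and the list was not called with an estimated correlation (adjusted p = 0.766), without Tdt control replicate 1 (adjusted p = 0.275) or without Utx KO replicate 2 (adjusted p = 0.0878). That 91.5% (54 of 59) of the measured macrophage, mural and endothelial markers had a negative log2 fold change restates the pattern, and the fluorescence sort is meant to remove such cells. The 3 most abundant markers of each of these 3 lists were not called (adjusted p from 0.126 to 0.815). Their log2 fold changes were 0.23 ± 0.11 for Cd14, -0.49 ± 0.16 for Lyz2, -0.22 ± 0.09 for Itgam, -0.04 ± 0.06 for Acta2, -0.35 ± 0.09 for Tagln, -0.65 ± 0.19 for Rgs5, -0.43 ± 0.13 for Cdh5, -0.20 ± 0.07 for Eng and -0.33 ± 0.12 for Pecam1. An effect of UTX loss in satellite cells that express these genes stays open and was not tested.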
